A study of Rattus with 18 samples.

How the data were processed

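Glomerular RNA of Sprague-Dawley rats (strain label SD, 200 g) was measured on 18 single-colour Agilent rat expression arrays, 1 array per sample. Per the labels, 30 rats received an antibody against Thy1, a surface protein of rat mesangial cells, and 6 received saline; glomeruli were taken on days 1, 2, 3, 4 and 5 after the antibody, and on day 0 from the saline controls. Per the labels, 3 glomeruli of each of 6 rats per time point were used, RNA was extracted with TRIzol, and 1.65 µg of RNA was amplified linearly and labelled with Cy3. Each of the 6 time points has 3 arrays. The labels do not say which rats lie behind an array, so p-values measure the spread between arrays of a day, which may be partly technical. Arrays are named by day and by the replicate number in their titles.

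Per the file headers, the intensity values of each array were made by the authors with Agilent Feature Extraction 10.7.3.1: the processed intensity is the spot brightness after background subtraction and spatial and multiplicative detrending within the array, with dim spots given a surrogate value above 0, and with no scaling between arrays. The mean spot intensity and the local background intensity are deposited in the same files and were used for an alternative background correction. The deposited value table holds log2 values whose source steps are not given in the sources used here. Its columns rank the probes as the arrays' processed intensities do and share their quantiles within 2 sets, days 0, 2 and 4 (median 5.493) and days 1, 3 and 5 (median 5.313), so that it reads as log2 values normalized to common quantiles in each set separately. No centring by gene was seen; the table was used only as an alternative and only within a set. The slide and scan-day fields show 5 slides and 2 scan days, numbered here in order. The headers name genome build rn4; probe positions were not used. Slide 1 held the 3 day 0 arrays and day 1 replicate 1, slide 2 held day 1 replicates 4 and 5 with day 3 replicates 2 and 3, slide 3 held day 3 replicate 4 and the 3 day 5 arrays, slide 4 held the 3 day 2 arrays and day 4 replicate 1, and slide 5 held day 4 replicates 2 and 3. Days 0, 1, 3 and 5 were scanned on scan day 1, days 2 and 4 on scan day 2.

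The processed intensity was converted to log2, and the array's 75th percentile over non-control spots was subtracted, which makes a log2 value of 0 equal to that percentile. Control spots and spots with an outlier flag (80 to 142 per array) were left out and spots of a probe were averaged. A probe entered if it was well above background, by the flag in the files, on all arrays of at least one time point, taken over its 3 arrays; 27837 of 41012 probes passed. Probe names were updated by RefSeq accession or symbol through the reference table of rat genes: 21786 probes matched, of which 18028 matched by the accession of their target, 467 by another accession, 2903 by symbol and 388 by an older symbol, and 19226 did not match. A gene was represented by its probe with the highest mean over the 18 arrays, which left 23186 genes and transcripts, 12232 of them with a current symbol, and 57 missing values. Of the named genes, 45 had more than 1 probe, and in 23 of these the probes differed in sign on some day; such genes are pointed out where they are named for such a day.

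The precision rests on 3 arrays per day; an array gives no count of molecules. The 75th percentile of the processed signal lay between 180.7 and 452.4, between 55.2% and 69.6% of probes were well above background on an array (22648 to 28530 probes), and no probe was saturated. The 3 controls had the lowest 75th percentiles (188.8, 180.7 and 229.2), and the lowest of the other arrays was 251.9. Correlations (Pearson, across the probes well above background on all 18 arrays, which are not independent replicates) between arrays of 1 day were between 0.952 and 0.9911; the lowest were those of day 0 replicate 4 with the other controls, 0.952 and 0.9583.

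The 6 groups were fitted together with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with the package data.table (version 1.17.8). Each day was contrasted with day 0, each day with the day before it, and a moderated F-test covered all time points; adjusted p is Benjamini-Hochberg within a contrast, with a threshold of 0.05. Errors beside log2 changes are standard errors of the fit (SE), with n = 3 arrays per group. Where a probe was not well above background on any array of a group, the change is given as a bound, "at least N-fold": the brighter group's mean against the dimmer group's mean of, per array, the higher of the lowest signal well above background and the probe's own. The genes given as a bound passed the threshold in the fit, and their adjusted p is not printed. A set of 28 gene lists (cell type markers, cell cycle, inflammation, matrix and metabolism) was tested with limma's camera, with the correlation between members estimated from the data and Benjamini-Hochberg adjustment over the lists of a contrast. Beside each list stand the number of measured members past the threshold over all genes and the number adjusted over the list alone. The list mean is the mean log2 change of its measured members. Members not on the array or too dim at every time point were left out, while a member bright at 1 time point could enter. That can raise the share of a list that changed. Measured were 22 of 28 chemokines, cytokines and adhesion molecules and 8 of 18 neutrophil markers. For lymphocyte and NK cell markers, and for matrix proteases and inhibitors, it was 15 of 20 each.

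The groups, tests, gene lists and first set of other settings were fixed before the data were examined, as was the rule for the genes named. For each day against day 0 these were the 8 largest rises and 8 largest falls among genes with a symbol past the threshold, whose 3 arrays lay on one side of the 3 controls and were well above background on all 6; the 2 members with the largest change past the threshold in each list; and Thy1, Itga8, Pdgfrb, Acta2, Nphs1, Pecam1, Cd68, Mki67, Fn1, Col1a1, Col4a1 and Tgfb1 whatever their result. Between successive days these were the 4 largest rises and 4 largest falls. Acta2 was not analysed here. The text names a part of these genes, and those named outside the rule are said to be so. Where one of the 11 genes analysed whatever their result passed only under another setting, the text gives a part of those settings; array weights and removal of 4 arrays together gave further such calls.

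The other settings fixed at that time, 18 apart from leaving out each of the 18 arrays in turn, were quantile normalization, scaling to the median, normexp background correction (offset 50), the authors' table, other filters on dim probes, a floor, flagged spots kept, the mean of a gene's probes, the 6 arrays of a comparison alone, eBayes with trend and robust settings, slide as a random block (duplicateCorrelation, statmod 1.5.0) or a fixed block, the replicate number as a block, an added 2-fold threshold, camera with a preset correlation of 0.01, and fry in either of its tests. A further 8 were added after seeing the data, together with 3 contrasts between days of 1 scan day; they are scaling to 12 reference genes, removal of a trend on probe GC content, a filter on bright genes, removal of arrays in doubt, array weights, the arrays of scan day 1 alone, and a normexp correction with flagged local backgrounds replaced. The fit was tested on simulated data for day 1 against day 0 with 23129 genes. Of 100 genes changed by a log2 of 1, 40% were recovered, and of 100 changed by a log2 of 2, 84%, with 10 false calls. These genes were drawn independently and few were changed, whereas 9265 were called on day 1 in the data. The recovered shares and false calls therefore do not carry over to the data. Camera, tested on simulated data with independent genes, called 0 of 28 unchanged lists and found the list shifted by 1 (adjusted p = 6.9e-06). Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.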

Results

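Gene expression in rat glomeruli was measured over the 5 days that follow an antibody against Thy1, a surface protein of mesangial cells, the contractile cells that hold the capillary loops of the glomerulus together. The labels describe a time course of anti-Thy1 nephritis, with day 0 as the control, and each comparison asks how glomerular transcripts differ between 2 time points. There were 18 arrays, 3 for each of days 0, 1, 2, 3, 4 and 5, so that n = 3 arrays per group throughout, and the number of arrays limits the precision. Between 22648 and 28530 probes were well above background on an array. Of 23186 genes and transcripts tested, 12308 (53.1%) changed over the time course by the moderated F-test.

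The controls shared slide 1 with 1 array of day 1. Days 2 and 4 were scanned on another day than the rest, and a part played by the scan day in their changes against day 0 cannot be told apart. Scan day as the whole cause is argued against. Day 2 differed from days 1 and 3 in 95 and 75 genes, and day 4 from days 3 and 5 in 693 and 643. From day 0, of the same scan day as days 1, 3 and 5, days 2 and 4 differed in 10651 and 12118 genes. The share of rises among called genes depended on the scaling between arrays. It lay between 45.3% and 48.9% with the 75th percentile, between 70% and 75.8% after scaling to the median, which moved the median change of all genes by 0.33 to 0.42. It lay between 11.3% and 20.5% after scaling to 12 reference genes, which moved it by -0.54 to -0.35. Removal of a trend on probe GC content gave between 54.6% and 58.8%, normexp background correction between 5.4% and 50%, and its repaired form between 34.7% and 40.5% (shift of -0.25 to -0.16). Changes against day 0 also followed brightness, by 5 bins of genes. The median change of the dimmest bin lay between -0.75 and -0.64 over the 5 days (1727 to 2109 genes lower, 148 to 351 higher). That of the brightest bin lay between 0.35 and 0.52. The bins were made from the mean signal over all arrays, those of the later days included. A gene that fell is thereby moved towards the dim bins, and one that rose towards the bright ones. A part of this trend is therefore fixed by the bins, and the size of that part was not tested. The 3 controls had the lowest 75th percentiles before scaling (188.8, 180.7 and 229.2, against 251.9 or more on the others). This difference in signal went with every comparison with day 0. Changes are relative to the 75th percentile of an array unless another scaling is named. No list of genes passed camera with an estimated correlation in any of 252 tests: 0 passed, 9 had an unadjusted p under 0.05, 85 passed with a preset correlation, 56 passed fry's directional test and 126 its test for either direction.

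On day 1, genes of macrophages, chemokines and DNA replication were higher than in the controls, and mesangial markers and genes of fatty acid oxidation were lower. Gpnmb, a glycoprotein of macrophages, was 68.7-fold higher (log2 6.1 ± 0.9 SE, adjusted p = 0.0013), and Ccl2, which attracts monocytes, 17.8-fold (4.16 ± 0.47, 0.00042). Thy1 itself fell by 3.25 ± 0.59 (9.51-fold, 0.0026), the mesangial integrin Itga8 by 3.66 ± 0.48 (12.6-fold, 0.00087), and the PDGF receptor Pdgfrb by 1.75 ± 0.39 (3.36-fold, 0.0052); Thy1 and Itga8 were each well above background on 2 of the 3 arrays of day 1. Pdk4, a brake on glucose oxidation, fell by 4.75 ± 0.89 (0.0028).

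Of 22 macrophage markers 16 rose on day 1 (16 adjusted over the list alone, mean 2.21), among them Cd68, a lysosomal protein of macrophages (2.48 ± 0.56, adjusted p = 0.0055), and Tyrobp, a signalling adaptor of myeloid cells (3.2). Of 22 chemokines, cytokines and adhesion molecules 15 rose and 1 fell (17 and 1 over the list alone, mean 1.78), with Ccl7, well above background on 2 of the 3 controls, at 4.7 and the cytokine Il1b at 3.32 ± 0.33. Sele, the E-selectin of activated endothelium, was at least 15.4-fold higher. Of 23 DNA replication genes 18 rose (19 over the list alone, mean 1.75), and Mcm5, a subunit of the replicative helicase, was at least 4.05-fold higher. Of 16 mesangial markers 8 fell (9 over the list alone, mean -1.17). Of 20 genes of fatty acid oxidation 6 fell (6 over the list alone, mean -1.06). Creb3l3, a transcription factor of lipid metabolism outside the lists, fell by 5.41 ± 0.78. Of 24 mitosis genes 2 fell (1 over the list alone), with a mean of 0.29 that turned to -0.15 after scaling to the reference genes, and the proliferation marker Mki67 stood at 0.76 (adjusted p = 0.38). Of 30 oxidative phosphorylation genes 19 rose and 1 fell (28 and 1 over the list alone), with a mean of 0.55 that went to 0.11 after scaling to the reference genes. Of 11 smooth muscle and myofibroblast genes 5 rose and 2 fell (the same over the list alone, mean 1.06), with the actin-binding Tagln at 3.3 ± 0.88.

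Of 26 podocyte markers 6 fell and 1 rose (5 and 1 over the list alone), with a mean of -0.26 that turned to 0.08 after scaling to the median. Synpo, a podocyte actin-binding protein, fell by 1.38. Its signals were 1.02, 2.25 and 1.02 on control replicates 2, 4 and 5, so that its falls on this and later days leaned in part on replicate 4. The slit diaphragm protein Nphs1 stood at -0.31 (adjusted p = 0.24), passing at -0.56 without control replicate 4, at -0.67 with quantile normalization and at -0.75 after scaling to the reference genes. Of 24 endothelial markers 7 fell and 1 rose (6 and 1 over the list alone, mean -0.36). Pecam1, an endothelial junction protein, fell by 1.32 ± 0.35 (adjusted p = 0.011), and without control replicate 4 (-0.88) or day 1 replicate 1 (-1.13) it no longer passed. Fn1 stood at 0.66 (adjusted p = 0.27) and Col4a1, whose probes differed in sign on every day, at 0.4 (0.29). Col1a1, whose probes differed in sign on days 1, 2 and 5, stood at 1.52 (0.23), and Tgfb1 at 0.99 (0.05), no longer past the threshold without control replicate 4 (0.77) or 5 (1.04), or day 1 replicate 1 (0.94) or 4 (0.82). Adjusted p over the 28 lists lay between 0.42 and 0.97 with an estimated correlation. By limma 9265 genes (40%) changed on day 1, 4455 up and 4810 down. With slide as a fixed block, which leaves the comparison to the 1 day 1 array on the controls' slide, 0 genes passed (7383 at an unadjusted p under 0.05) and Thy1 stood at -3.06. On that array the mean of macrophage markers was 2.16 and that of mesangial markers -0.9. The count was 4617 without control replicate 4, 5391 without day 1 replicate 1, 4891 without day 1 replicate 4, 3306 in a fit of the 6 arrays alone and 29 after a normexp background correction (10999 in its repaired form).

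On day 2, mitosis genes stood far above the controls, macrophage and chemokine genes were higher, and Itga8 and Thy1 were lower. Gpnmb was 34-fold higher (5.09 ± 0.9, adjusted p = 0.0011), Mki67 8.47-fold (3.08 ± 0.68, 0.003), and Ccnb2, a cyclin that drives entry into mitosis, 10.4-fold (3.37, 0.0039). Itga8 fell by 2.41 ± 0.48 (0.0017) and Thy1 by 1.84 ± 0.59 (0.02), and without control replicate 4 (-1.56) or day 2 replicate 3 (-1.54) Thy1 no longer passed.

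Of 24 mitosis genes 21 rose on day 2 (22 over the list alone, mean 2.42), and of 23 DNA replication genes 20 rose (21 over the list alone, mean 2.12). Of 22 macrophage markers 18 rose (19 over the list alone, mean 2.22), with Cd68 at 2.31 (adjusted p = 0.0048), and of 15 lymphocyte and NK cell markers 10 rose (11 over the list alone, mean 1.72). Of 22 chemokines, cytokines and adhesion molecules 18 rose and 1 fell (19 and 1 over the list alone, mean 1.55), with Sele at least 12.2-fold higher. Of 18 immediate early genes 10 rose and 2 fell (the same over the list alone, mean 1.16), with the AP-1 subunit Fos at 3.46. Of 16 mesangial markers 4 fell (4 over the list alone, mean -0.59), and Pdgfrb stood at -0.72 (adjusted p = 0.14). Of 20 fatty acid oxidation genes 1 rose (0 over the list alone), with a mean of 0.18 that turned to -0.17 after scaling to the reference genes. Pf4, a platelet chemokine, rose by 3.7, and Grem1, a secreted antagonist of BMPs, by 2.37. Of 26 podocyte markers 5 fell and 2 rose (5 and 1 over the list alone), with a mean of -0.11 that turned to 0.26 after scaling to the median, and Synpo fell by 2.08 (adjusted p = 0.00071). Nphs1 stood at -0.11 (0.69), Pecam1 at -0.72 (0.11), Fn1 at 0.56 (0.34), Col1a1 at 2.11 (0.094), Col4a1 at 0.44 (0.24) and Tgfb1 at 0.91 (0.062). Nphs1 turned to 0.03 without control replicate 2 and 0.01 without control replicate 5. Pecam1 passed without control replicate 5 (-0.98) or day 2 replicate 2 (-1.01) and after scaling to the reference genes (-1.07), where Pdgfrb passed too (-1.08). Tgfb1 passed with quantile normalization (1.26), with the authors' table (1.23), without day 2 replicate 4 (1.19) and with the GC trend removed (1.4), where Col4a1 passed too (0.93). After scaling to the median Tgfb1 (1.28), Col1a1 (2.48) and Col4a1 (0.81) passed, as did Col1a1 in a fit of the 6 arrays alone (2.11). Adjusted p over the 28 lists lay between 0.69 and 0.91 with an estimated correlation. By limma 10651 genes (45.9%) changed, 4824 up and 5827 down, and 1485 changed after the normexp background correction (14034 repaired).

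On day 3, genes of macrophages, lymphocytes, the interferon response and the cell cycle were higher than in the controls, together with contractile genes. Gpnmb was 44.5-fold higher (5.47, adjusted p = 0.00066), Inhba, which encodes a subunit of activin A, 22.7-fold (4.51 ± 0.98, 0.0022), Tagln 19.6-fold (4.29 ± 0.88, 0.0016), and Edn1, the vasoconstrictor endothelin, 6.99-fold (2.8 ± 0.37, 0.00043). Itga8 fell by 2.5 (0.0012), while Thy1 stood at -0.46 (0.54) and Pdgfrb at 0.05 (0.93; -0.16 without control replicate 4 and -0.09 with quantile normalization).

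Of 22 macrophage markers 20 rose on day 3 (22 over the list alone, mean 2.82), with Cd68 at 2.89 (adjusted p = 0.0013) and C1qb, a chain of complement C1q, at 3.93. Of 15 lymphocyte and NK cell markers 12 rose (13 over the list alone, mean 2.2), with the cytotoxic protease Gzmb at 3.02. Of 20 interferon response genes 15 rose (16 over the list alone, mean 1.35), with the GTPase Gbp2 at 2.39 and the immunoproteasome subunit Psmb8 at 2.16, and of 6 MHC class II genes 5 rose (5 over the list alone, mean 1.37), with RT1-Da at 2.22. Of 23 DNA replication genes 23 rose (23 over the list alone, mean 2.21), and of 24 mitosis genes 21 rose (22 over the list alone, mean 2.63), with Mki67 at 2.53 (0.0076) and Ccnb2 at 3.72. Of 11 smooth muscle and myofibroblast genes 7 rose and 2 fell (8 and 2 over the list alone, mean 1.66), with the tropomyosin Tpm2 at 3.88. Of 28 matrix genes 10 rose and 1 fell (8 and 1 over the list alone, mean 0.88), with the collagen cross-linking enzyme Loxl2 at 2.87. Col1a1 at 2.51 (0.048) and Col4a1 at 0.9 (0.022) passed but no longer did with quantile normalization (2.41 and 0.58), without day 3 replicate 2 (1.95 and 0.82) or without control replicate 4 (2.01 and 0.75). The 3 probes of Col1a1 lay between 0.6 and 2.51, and the value given is the highest. Without control replicate 5 (2.6) or day 3 replicate 3 (2.49) Col1a1 did not pass, nor did Col4a1 without day 3 replicate 4 (0.85). Tgfb1, a profibrotic cytokine, rose by 1.34 (0.01), but not without control replicate 4 (1.11). Of 19 complement genes 11 rose and 1 fell (13 and 2 over the list alone, mean 1.23), with the anaphylatoxin receptor C5ar1 at 3.69. Of 17 markers of loop, distal tubule and collecting duct 7 fell (7 over the list alone, mean -0.59).

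Of 16 mesangial markers 3 rose and 3 fell on day 3 (the same over the list alone), with a mean of 0.05 that turned to -0.42 after scaling to the reference genes. Of 26 podocyte markers 6 fell and 1 rose (the same over the list alone), with a mean of -0.18 that turned to 0.22 after scaling to the median; Synpo fell by 1.79 and Nphs1 stood at -0.09 (adjusted p = 0.74), or 0.04 and 0.03 without control replicates 2 and 5. Pecam1 stood at -0.61 (0.17) and Fn1 at 1.08 (0.068). Fn1 passed without control replicate 2 (1.4), after scaling to the median (1.47), with the repaired normexp (1.14) and in a fit of the 6 arrays alone (1.08). After scaling to the reference genes Pecam1 (-1.08) and Nphs1 (-0.56) passed. Adjusted p over the 28 lists lay between 0.35 and 0.99 with an estimated correlation. By limma 11067 genes (47.7%) changed, 5042 up and 6025 down. With slide as a fixed block 1 gene passed, and the mean was 2.62 for macrophage markers, 3.16 for mitosis genes and 0.52 for interferon response genes; 1544 genes changed after the normexp background correction (14052 repaired).

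On day 4, contractile and matrix genes were higher than in the controls, and the endothelial genes Ehd3 and Pecam1 were lower. Ccl20, which attracts lymphocytes and dendritic cells, was 28.7-fold higher (4.84 ± 0.57, adjusted p = 0.00015), Grem1 15.7-fold (3.97 ± 0.48, 0.00015), and Fn1, the matrix protein fibronectin, 3.24-fold (1.7 ± 0.47, 0.0075). Ehd3, an endocytic protein of glomerular endothelium, fell by 2.81 ± 0.39 (0.00021) and stood at -2.22 without control replicate 4. Pecam1 fell by 1.68 ± 0.35 (0.0015). Its signals were 0.06, 1.29 and -0.12 on control replicates 2, 4 and 5, so that this fall leaned in part on replicate 4.

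Of 28 matrix genes 14 rose and 1 fell on day 4 (14 and 1 over the list alone, mean 1, or 1.38 without day 4 replicate 1). Col1a1 rose by 2.98 ± 0.99 (adjusted p = 0.02) and stood at 4.16 without day 4 replicate 1, and it did not pass without control replicate 4 (2.49) or day 4 replicate 2 (2.73) or 3 (2.07). Its 3 probes lay between 0.63 and 2.98, and the value given is the highest. Col4a1 stood at 0.83 (0.03) and no longer passed with quantile normalization (0.36), nor without control replicate 4 (0.68) or 5 (0.83) or day 4 replicate 2 (0.67) or 3 (0.7). Of 11 smooth muscle and myofibroblast genes 7 rose and 2 fell (7 and 2 over the list alone, mean 1.51, or 2 without day 4 replicate 1), with Tagln at 3.74 (0.0029), 4.87 without day 4 replicate 1 and 3.14 without day 4 replicate 2. Of 30 oxidative phosphorylation genes 25 rose and 1 fell (26 and 1 over the list alone), with the complex I subunit Ndufb5 at 1.22 and a mean of 0.71 that went to 0.17 after scaling to the reference genes, whose own mean was 0.54. Of 24 endothelial markers 8 fell (6 over the list alone, mean -0.56). Of 26 podocyte markers 7 fell and 3 rose (the same over the list alone), with a mean of -0.17 that turned to 0.23 after scaling to the median, and Lmx1b, a podocyte transcription factor, fell by 1.95 ± 0.24 (0.00015). Of 16 mesangial markers 5 rose and 1 fell (3 and 1 over the list alone), with a mean of 0.54 (0.86 without day 4 replicate 1) that went to 0 after scaling to the reference genes. Thy1 stood at 0.37 (0.62; -0.27 without day 4 replicate 2), Pdgfrb at 0.53 (0.26), and Itga8 fell by 1.8 (0.0061).

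Macrophage and mitosis genes differed between the arrays of day 4: the mean of macrophage markers above the controls was -0.13 on replicate 1, 1.83 on replicate 2 and 1.59 on replicate 3. That of mitosis genes was -0.04, 2.15 and 2.21. Of 22 macrophage markers 7 rose (1 over the list alone, mean 1.1), and Cd68 stood at 0.85 (adjusted p = 0.21) with the 3 arrays and passed at 1.42 without replicate 1. Of 24 mitosis genes 9 rose (1 over the list alone, mean 1.44), and Mki67 passed at 1.75 (0.043) but not without control replicate 4 (1.63) or 5 (1.64) or day 4 replicate 2 (1.51) or 3 (1.37). Of 22 chemokines, cytokines and adhesion molecules 11 rose and 1 fell (12 and 1 over the list alone, mean 1.08). Nphs1 stood at -0.25 (0.32), passing at -0.5 without control replicate 4, at -0.72 both with quantile normalization and with the authors' table and at -0.79 after scaling to the reference genes, and Tgfb1 at 0.31 (0.51). Adjusted p over the 28 lists lay between 0.73 and 0.97 with an estimated correlation. By limma 12118 genes (52.3%) changed, 5930 up and 6188 down; 2604 changed after the normexp background correction (15222 repaired) and 7814 with the replicate number as a block.

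On day 5, genes of fatty acid oxidation and the endothelial genes Ehd3 and Pecam1 were lower than in the controls, and Grem1 was higher. Creb3l3 fell by 5.92 ± 0.78 (adjusted p = 0.00063), while Grem1 was 7.06-fold higher (2.82 ± 0.48, 0.0011). Ehd3 fell by 2.39 (0.00097) and stood at -1.8 without control replicate 4. Pecam1 fell by 1.78 (0.0019), and this fall too leaned in part on control replicate 4, the control with the highest signal of Pecam1.

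Of 20 fatty acid oxidation genes 8 fell on day 5 (8 over the list alone, mean -1.04), with Pdk4 at -3.56 (adjusted p = 0.006). The list mean was lowest on replicate 5, as was that of proximal tubule markers (mean -0.19, from -0.83 to 0.32 over the arrays). A part played by the share of tubule RNA was not tested. With day 5 replicates 2 and 4 both left out Pdk4 (-2.99) no longer passed. Of 24 endothelial markers 5 fell (5 over the list alone), with a mean of -0.38 that turned to 0.04 after scaling to the median. Of 26 podocyte markers 7 fell and 3 rose (6 and 2 over the list alone), with a mean of -0.06 that turned to 0.36 after scaling to the median. Of 11 smooth muscle and myofibroblast genes 6 rose and 2 fell (the same over the list alone, mean 1.02, or 0.48 without replicate 5), with Tagln at 2.72 (0.022), 3.48 without replicate 2, and not past the threshold without replicate 5 (1.51) or control replicate 4 (2.64). Of 30 oxidative phosphorylation genes 19 rose and 1 fell (23 and 1 over the list alone, mean 0.57, or 0.19 after scaling to the reference genes), and of 23 DNA replication genes 11 rose (11 over the list alone, mean 1.08, or 0.54 without replicate 5). S100a9, a calcium-binding protein of neutrophils, rose by 2.59 (0.0035), but not with day 5 replicates 2 and 4 both left out (2.29). Of 28 matrix genes 4 rose and 1 fell (1 and 1 over the list alone, mean 0.73, or 0.22 without replicate 5), and Fn1 rose by 1.33 (0.031), but not without replicate 5 (0.72) or control replicate 4 (1.11) or 5 (1.25).

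The mean of macrophage markers above the controls was 0.31 on day 5 replicate 2, 0.02 on replicate 4 and 2.32 on replicate 5. That of mitosis genes was -0.68, 0.43 and 2.43. Of 22 macrophage markers 2 rose (1 over the list alone, mean 0.88), and of 24 mitosis genes 1 rose and 1 fell (0 and 1 over the list alone, mean 0.72). Of 16 mesangial markers 1 rose and 1 fell (0 and 0 over the list alone), with a mean of 0.38 (0.06 without replicate 5) that went to 0 after scaling to the reference genes. Cd68 stood at 0.89 (adjusted p = 0.2; 0.24 without replicate 5), Mki67 at 0.3 (0.74; -0.61 without replicate 5), and Thy1 at -0.58 (0.44). Pdgfrb stood at 0.47 (0.33), Nphs1 at 0.18 (0.5), Col1a1 at 1.01 (0.42; -0.09 without replicate 5), Col4a1 at 0.69 (0.071) and Tgfb1 at 0.86 (0.076). Nphs1 turned to -0.25 with quantile normalization and -0.08 without control replicate 4, and passed at 0.6 after scaling to the median. Col4a1 passed without replicate 2 or 4 (0.88 for each), after scaling to the median (1.12), with the GC trend removed (1.02) and with the repaired normexp (0.81). Tgfb1 passed with quantile normalization (1.24), after scaling to the median (1.29) and with the GC trend removed (1.19). With day 5 replicates 2 and 4 both left out Cd68 (2.2), Mki67 (2.1), Col4a1 (1.45) and Tgfb1 (1.57) passed, and Thy1 turned to 0.51. Itga8 stood at -1.3 (0.038) and no longer passed with quantile normalization (-1.09), nor without control replicate 2 (-1.3) or 4 (-0.9) or any 1 array of day 5 (-1.42, -1.2 and -1.27). Adjusted p over the 28 lists lay between 0.76 and 0.94 with an estimated correlation. By limma 10263 genes (44.3%) changed, 4845 up and 5418 down. With slide as a fixed block 1 gene passed, the mean of macrophage markers was 0.43, that of mitosis genes 1.69 and Thy1 stood at 0.58. The count was 6515 without control replicate 4, 4813 in a fit of the 6 arrays alone and 56 after the normexp background correction (12135 repaired).

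**Figure D1:**
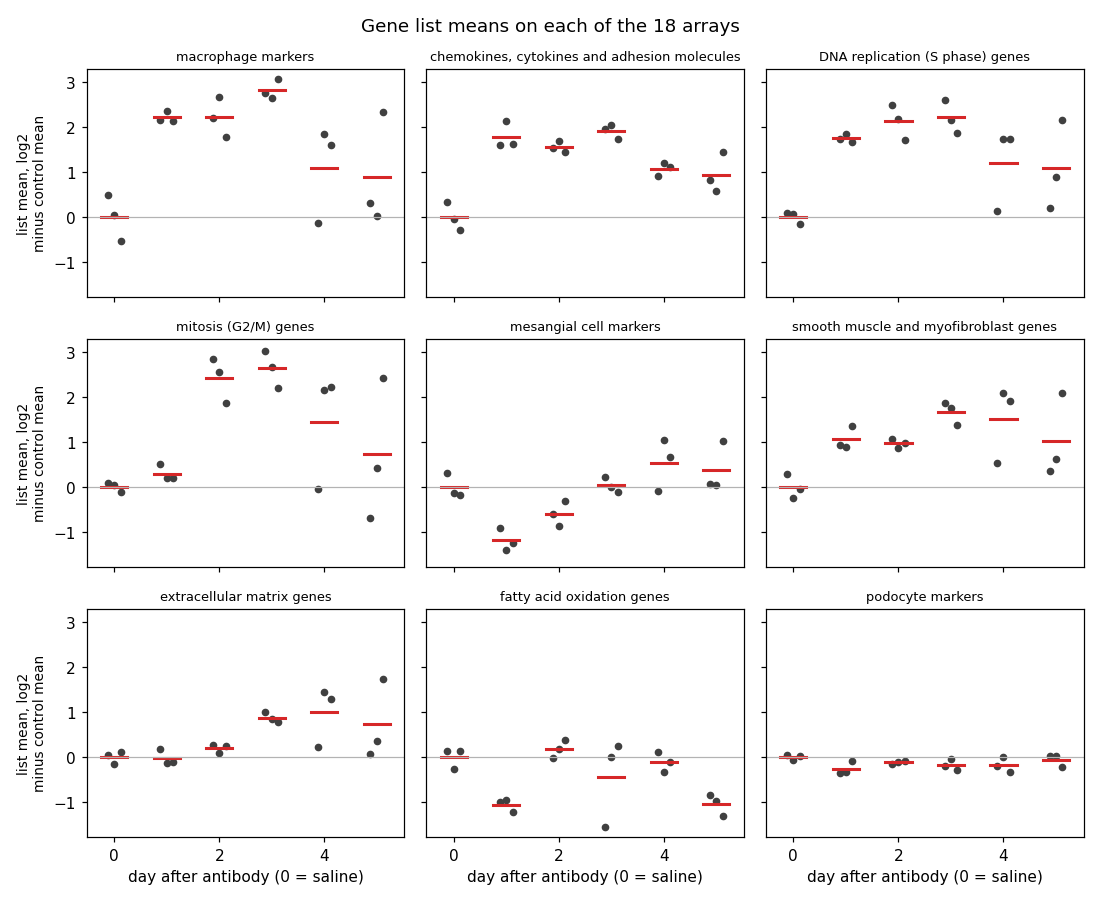
Mean log2 change of 9 gene lists on each array, relative to the mean of the 3 controls, against the day; points are arrays and bars are group means. Podocyte means of days 1 to 5 are negative here and turn positive after scaling to the median (0.08, 0.26, 0.22, 0.23 and 0.36), those of mitosis on day 1, matrix on days 1 and 2 and fatty acid oxidation on days 2 and 4 also turn under a scaling, the mesangial mean turns on day 3, and macrophage means of day 5 arrays lie between 0.02 and 2.32.

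**Figure D2:**
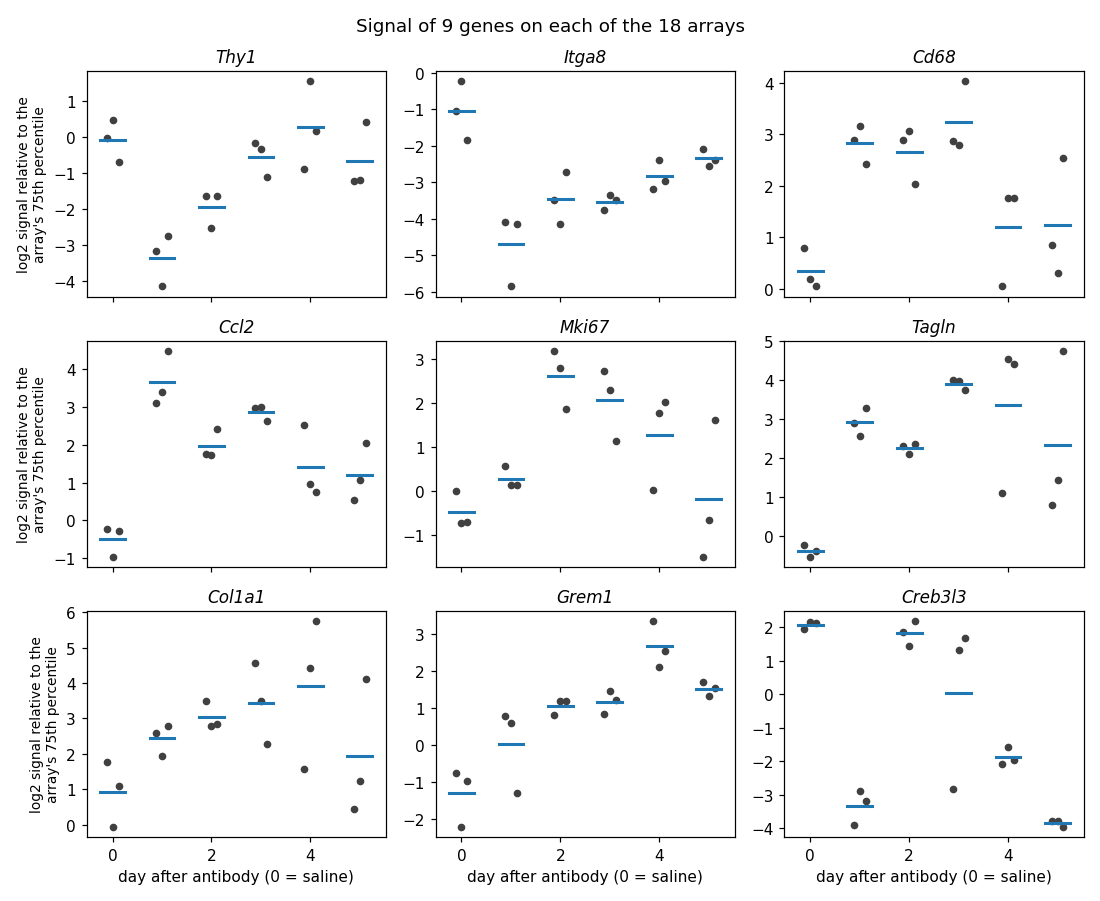
Log2 signal of 9 genes relative to the array's 75th percentile on each array, against the day; points are arrays and bars are group means. Thy1 and Itga8 are lowest on day 1, at -3.25 and -3.66 from the controls, and Creb3l3 is low on days 1, 4 and 5 (-5.41, -3.95 and -5.92) and on day 3 replicate 2 (signal of -2.83), of which days 3 and 4 lie outside the rule for named genes.

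Between successive days, the named genes with large differences included genes of fat metabolism, chemokines and the ribosomal protein gene Rps26. From day 1 to day 2 Creb3l3 rose by 5.14 (adjusted p = 0.015) and Pdk4, whose probes differed in sign on day 2, by 4.87 (0.033), and Ccl7 fell by 3.04 (0.049). From day 3 to day 4 Ccl20 rose by 2.47 (0.035) and Cxcl13, a B cell chemokine, by 2.9 (0.026), while Edn1 fell by 2.6 (0.0044) and Dnase1l3, a secreted DNase, by 4.13 (0.0069). From day 4 to day 5 Ccl20 fell by 4.45 (0.0018). Rps26 fell by 3.77 from day 2 to day 3, rose by 3.78 from day 3 to day 4 and fell by 4.61 from day 4 to day 5. Il2rg, the common chain of several interleukin receptors, rose by 0.97 from day 2 to day 3 (0.0065).

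From day 1 to day 2, 1 of 24 mitosis genes rose (23 adjusted over the list alone, mean 2.12), and 2 of 20 fatty acid oxidation genes rose (10 over the list alone, mean 1.24). From day 3 to day 4, 3 of 22 macrophage markers (18 over the list alone, mean -1.72), 4 of 20 interferon response genes (15 over the list alone, mean -1.15) and 2 of 24 endothelial markers (11 over the list alone, mean -0.65) fell, and among chemokines 1 rose and 4 fell (2 and 13 over the list alone). From day 4 to day 5, 3 of 20 fatty acid oxidation genes fell (7 over the list alone, mean -0.93), and 2 of 17 markers of loop, distal tubule and collecting duct rose (7 over the list alone, mean 0.54). The adjusted p of the lists between successive days was between 0.83 and 0.98, 0.75 and 0.87, 0.32 and 0.97, and 0.97 and 1 in turn, with an estimated correlation. By limma 95 genes changed from day 1 to day 2 (42 up, 53 down), 75 from day 2 to day 3 (18 up, 57 down), 693 from day 3 to day 4 (377 up, 316 down) and 643 from day 4 to day 5 (165 up, 478 down). Each of these comparisons crosses the 2 scan days, so that day and scan day cannot be told apart. With the replicate number as a block the counts were 2, 10, 24 and 27, and after the normexp background correction 0, 2, 4 and 1 (3800, 444, 1278 and 3756 at an unadjusted p under 0.05), or 132, 79, 997 and 694 in its repaired form. Leaving out 1 array in turn gave 10 to 82, 7 to 63, 96 to 499 and 220 to 593, and array weights 1811, 1620, 3816 and 3500.

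Comparisons within a scan day were added after the scan days had been seen, and few genes passed in them. From day 2 to day 4, Angpt2, a ligand of the endothelial receptor Tie2, rose by 2.51 and Agtr1a, an angiotensin II receptor, by 1.46, while Lyve1, a hyaluronan receptor, fell by 1.86 (adjusted p = 0.012). From day 1 to day 3 24 mitosis genes had a mean of 2.34 and 16 mesangial markers one of 1.22; by limma 0 members of either passed over all genes, 24 and 9 were higher over the list alone, with adjusted p = 0.3 for both with an estimated correlation. From day 3 to day 5 macrophage markers had a mean of -1.94 (19 lower over the list alone) and interferon response genes one of -1.24 (13 lower over the list alone), with adjusted p = 0.17 for both with an estimated correlation. By limma 1 gene changed from day 1 to day 3, 2 from day 3 to day 5 and 23 from day 2 to day 4 (14 up, 9 down), against 3165, 3064 and 3225 at an unadjusted p under 0.05.

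The remaining lists are given for day 3. Of 15 matrix proteases and inhibitors 6 rose and 1 fell (the same over the list alone, mean 1.05). Of 16 oxidative stress response genes 7 rose and 1 fell (the same over the list alone, mean 0.66), with the heme-degrading Hmox1 at 3.49, and of 15 p53 targets and apoptosis genes 5 rose (4 over the list alone, mean 0.57). Of 28 growth factors and receptors 10 rose and 4 fell (the same over the list alone), with a mean that turned to -0.08 after scaling to the reference genes, and Tgfb3 stood at 3.41. Of 15 glycolysis genes 5 rose and 1 fell (the same over the list alone), with a mean that turned to -0.23 under that scaling, and of 15 vasoactive and renin-angiotensin genes 3 rose and 2 fell (2 and 2 over the list alone), with a mean that turned to -0.21. Of 10 platelet and red cell markers 4 rose and 1 fell (the same over the list alone, mean 0.61). Of 8 neutrophil markers 1 rose and 1 fell, of 10 parietal epithelial markers 2 rose and 2 fell, and of 20 proximal tubule markers 1 rose and 2 fell (over the list alone 1 and 1, 2 and 2, and 0 and 1), and the direction of each of these 3 means turned with the scaling. Of 12 reference genes 9 rose and 1 fell (10 and 1 over the list alone, mean 0.47, at 0 by construction after scaling to them). Oxidative phosphorylation genes, given above for days 1, 4 and 5, had lower means on day 2 (0.38) and day 3 (0.23). Their mean on day 3 turned to -0.11 with quantile normalization and to -0.24 after scaling to the reference genes. The adjusted p of these lists lay within the range given for day 3, with an estimated correlation.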

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

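The comparisons within a scan day, the counts of other splits and all tests of slide, mix-up, tubule RNA, scaling and scan day were chosen only after the result was seen, while the tests of brightness, genomic DNA and probe GC content were written down before theirs was computed.

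The change against day 0 differed between successive days, tested directly, in 95 genes between days 1 and 2, 75 between days 2 and 3, 693 between days 3 and 4 and 643 between days 4 and 5. Within a scan day it differed in 1 gene between days 1 and 3, in 2 between days 3 and 5 and in 23 between days 2 and 4. Slc4a8, a bicarbonate transporter gene, was lower on day 3 than on day 1 (-1.67), and Sult5a1, a sulfotransferase gene, was higher on day 5 than on day 3 (1.81). Day 4 exceeded day 2 in Angpt2 (2.51), Cpe (2.37), B3galt2 (1.76) and Agtr1a (1.46), and lay below it in Atp12a (-3.39), Lyve1 (-1.86), Syk (-1.19) and Cacnb2 (-1.04).

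Each comparison of 3 arrays with 3 has 10 splits, too few for a share under 0.05. The real split gave 9265 genes on day 1, 10651 on day 2, 11067 on day 3, 12118 on day 4 and 10263 on day 5 against day 0, and the highest other split 1, 0, 2, 0 and 1. Between successive days the real split gave 95, 75 and 693 genes and the highest other split 0 in each, while from day 4 to day 5 the real split gave 643 and another split 1326. From day 3 to day 5 the real split gave 2 genes and another 326, from day 1 to day 3 they gave 1 and 2, and from day 2 to day 4 they gave 23 and 0. The splits of days 4 and 5 and of days 3 and 5 that call many more genes point to a structure of the samples. The 1326 came from day 4 replicate 1 with day 5 replicates 2 and 4 set against the other arrays of these days, which lie on slides 3 and 4 against slides 3 and 5. The 326 came from day 3 replicate 4 with day 5 replicates 2 and 4, all on slide 3, set against day 3 replicates 2 and 3 on slide 2 and day 5 replicate 5 on slide 3. For the time course 1 of 100 drawn splits, the real one, gave as many genes (12308 against a highest other of 6386). That argues against a random assignment of the arrays to days. The draws exchanged arrays freely, although slide and scan day go largely with the day. They therefore cannot tell the day apart from slide, scan day or differences between rats.

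Day 4 replicate 1 and day 5 replicates 2 and 4 lay near the control level of macrophage and mitosis genes, unlike the other arrays of their days. Their means of matrix genes (0.23, 0.08 and 0.36, against 1.3 to 1.74 on the other arrays) were lower too. For day 5, slide is argued against by a gap of 2.3 in the macrophage mean between arrays on 1 slide. For day 4 replicate 1, whose macrophage mean lay below the nearest array of day 4 (-1.72), no other array of day 4 was on its slide. The 3 day 2 arrays on that slide had macrophage means of 1.78 to 2.67 and mitosis means of 1.86 to 2.83, so that the slide did not bring these genes to the control level on all its arrays. A shift of the slide that adds to a difference between days cannot be told apart from one of the array. A mix-up with a control array is argued against by the olfactory receptor transcripts, whose median on these 3 arrays was at most -1.18, against -0.34 to 0.64 on the controls. These transcripts were chosen after they were seen to be lower on every day, these arrays included, so that the test is not independent of that choice. Proximal tubule markers were higher on these arrays (0.63, against -0.21 and 0.27 on day 4; 0.32 and -0.06, against -0.83 on day 5), as were parietal markers (0.85, against 0.2 and 0.43; 0.5 and 0.62, against -0.03). Dilution by tubule RNA as the whole cause is argued against by the podocyte mean, which lay at most 0.2 below the highest array of the day (-0.2), while the macrophage mean fell short by more. A difference between rats in the course of the disease may remain, and was not tested, since the labels do not say which rats lie behind an array.

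Genes differed between days 2 and 4 and days 1, 3 and 5: that split of the days called 1360 genes (861 up, 499 down), and the highest other split of 2 days from 3 called 722. Rps26 (3.78) was higher on days 2 and 4, and Ccno, whose probes differed in sign on days 1 and 5 (-2.41), and the complement gene C6 (-1.88) were lower, genes chosen after their values were seen. Probe GC content is argued against as the whole cause, since after removal of its trend that split still called 955 genes against 516. The scan day may account for the pattern, but it cannot be told apart from a difference of the days themselves, or from any other step that the arrays of days 2 and 4 shared.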

How the results depend on the processing

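Of 205 counts under the settings fixed beforehand 148 stayed within 1.5 times the reported count and 57 did not; of 4676 list means 4434 stayed within their spread, 235 moved and 7 reversed; of 7702 values of named genes 6572 kept direction and side of the threshold, 1062 no longer passed, 24 newly passed, 29 moved and 15 reversed. A further 8 settings, chosen after seeing the data (scaling to the reference genes, GC trend removed, genes above the 75th percentile, arrays left out together, array weights, scan day 1 alone, repaired normexp), reversed 26 list means and 10 genes. Signal over background limits the dim genes: between 55.2% and 69.6% of probes were well above it. The authors' table gave 8467 genes on day 2 and 9890 on day 4; it gives no other comparison with day 0. Where no cause is named, the cause was not tested.

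The normexp correction gave 29, 1485, 1544, 2604 and 56 genes on days 1 to 5, 0, 2, 4 and 1 between successive days, 854 over the time course and 8 list tests; spots with a flagged background near saturation (lowest difference -65207 on day 1 replicate 1 and -60130 on day 5 replicate 5) had pulled the fitted means of these arrays to -910 and -798. With flagged backgrounds replaced, a repair chosen after that result, it gave 10999, 14034, 14052, 15222 and 12135 genes, then 132, 79, 997 and 694, and 15675. Without a filter 58, 46 and 374 genes changed on days 2, 3 and 4 against the day before, and with probes above background on all 18 arrays 61 and 43 on days 2 and 3. With the 6 arrays of a comparison alone, a fit with fewer samples, 3306 changed on day 1 and 4813 on day 5, 350, 35 and 14 on days 2, 3 and 4 against the day before, and 2 list tests passed. With slide as a fixed block 0, 1 and 1 changed on days 1, 3 and 5 by limma (7383, 6747 and 4570 at an unadjusted p under 0.05), since the controls' slide holds 1 other array. With the replicate number as a block, which does not pair the arrays (correlations of -0.38 to 0.28), 6372, 7939, 8726, 7814 and 9054 changed on days 1 to 5, 2, 10, 24 and 27 between successive days and 6872 over the time course. Scaling to the reference genes gave 184 and 162 on days 2 and 3 against the day before and 4 list tests, and removal of the GC trend 28 and 28. Among genes above the 75th percentile, fewer genes by construction, 3822, 3504, 3960, 4734 and 4220 changed on days 1 to 5, 19, 14, 309 and 251 between successive days and 4724 over the time course. Without day 5 replicates 2 and 4 together 33 changed from day 4 to day 5. Without these, control replicate 4 and day 4 replicate 1, which leaves 1 array on day 5, assumed to vary like the other groups, 5426 changed on day 1, 6193 on day 5, 218 from day 3 to day 4 and 23 from day 4 to day 5. Array weights, estimated gene by gene after the default estimate did not converge, gave 1811, 1620, 3816 and 3500 between successive days and 19136 over the time course. At least 2-fold were 4195, 5640, 5864, 6509 and 4606 genes. List tests passed 85 times with a preset correlation, 56 by fry's directional test and 126 by its test for either direction.

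Leaving out arrays in turn gave 4617 to 9643 genes on day 1, 7137 to 10859 on day 2, 8373 to 11151 on day 3, 9317 to 12102 on day 4 and 6515 to 10565 on day 5; 10 to 82, 7 to 63, 96 to 499 and 220 to 593 between successive days; and 9224 to 12940 over the time course. On day 1 the count was 4617 without control replicate 4, 5391 without replicate 1 and 4891 without replicate 4, and on day 5 it was 6515 without control replicate 4. From day 1 to 2 it was 13 and 20 without day 1 replicates 4 and 5, and 20, 11 and 10 without day 2 replicates 2, 3 and 4. From day 2 to 3 it was 16, 21 and 7 without day 2 replicates 2, 3 and 4, and 33 without day 3 replicate 4. From day 3 to 4 it was 374, 446 and 134 without day 3 replicates 2, 3 and 4, and 96 and 185 without day 4 replicates 1 and 3. From day 4 to 5 it was 303, 292 and 220 without day 4 replicates 1, 2 and 3, and 248 and 237 without day 5 replicates 2 and 4.

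Results that reversed were these. After scaling to the median the podocyte mean was 0.08, 0.26 and 0.22 on days 1 to 3 and the endothelial mean 0.04 on day 5. After normexp, from day 1 to 2, growth factors had a mean of -0.06 and glycolysis genes 0.18; Foxi1 was 0 and Fgf2 0.17 on day 1, Trpc6 -0.11, Itgam -0.14 and Cd79b -0.02 on day 2, Cdc6 -0.02, Kif2c -0.09, Nusap1 -0.07, Masp1 -0.15, Ciita -0.18 and Fosl1 -0.38 on day 4, and Ciita 0.28 on day 5. After the repaired normexp Trpc6 was -0.05 and Itgam -0.07 on day 2, Cdc6 -0.02, Kif2c -0.11, Nusap1 -0.07, Masp1 -0.14, Ciita -0.17 and Fosl1 -0.38 on day 4, and Gins2 -0.02 on day 5. With probes above background on all arrays the oxidative stress mean from day 3 to 4 was 0.07, and among genes above the 75th percentile 0.19, where the neutrophil mean on day 1 was -0.3. With slide as a fixed block Ciita was 0.46 and Ptgds -0.41 on day 5. After scaling to the reference genes the means were -0.15 for mitosis on day 1; -0.19, -0.01 and -0.15 for p53 targets on days 1, 2 and 4; -0.05, -0.23, -0.18 and -0.05 for glycolysis on days 1, 3, 4 and 5 and -0.03 from day 2 to 3; -0.15 for matrix on day 2; -0.11, -0.08 and -0.07 for growth factors on days 2 to 4; -0.21 and -0.13 for vasoactive genes on days 3 and 4; -0.04 and -0.01 for parietal markers and -0.09 and 0 for oxidative stress on days 4 and 5; and 0 by construction for the reference genes. The parietal mean on day 5 was -0.03 without day 5 replicates 2 and 4 and -0.22 without the 4 arrays.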

Other observations

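The families of genes below, the tests of scaling between arrays and the comparison of protein synthesis and breakdown genes at matched brightness were chosen only after the result was seen; the olfactory receptor tests of brightness and of genomic DNA were not.

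Genes of protein synthesis and breakdown were higher than in the controls on each of the 5 days. Of 84 ribosomal protein genes 65, 63, 70, 75 and 66 rose on days 1 to 5 and 1 fell on each, with medians of 0.68, 0.67, 0.77, 0.81 and 0.74; the lowest median over the scalings was 0.24, so that the direction held. Of 37 proteasome subunits 28, 23, 32, 31 and 30 rose, with medians between 0.55 and 0.84 and a lowest median of 0.2 over the scalings. Of 51 translation initiation factors 29, 31, 30, 35 and 33 rose, with medians between 0.48 and 0.67 and a lowest of 0.04 over the scalings. Bright genes in general rose and dim ones fell: the median of the brightest of 5 bins of genes was 0.44, 0.35, 0.36, 0.52 and 0.48 on days 1 to 5, and that of the dimmest -0.64, -0.75, -0.75, -0.75 and -0.71. At matched brightness the 3 families lay above other transcripts by less, so that a part of each rise was shared with other genes of their brightness. The excess was 0.17 to 0.4 for ribosomal protein genes, 0.18 to 0.41 for proteasome subunits and 0.11 to 0.28 for translation initiation factors. Brightness was the mean over all arrays, later days included, which moves genes that rose towards the bright bins. A part of the trend with brightness, and so of the shared rise, is therefore fixed by the bins. The matched comparisons of olfactory receptors and of transcripts without a symbol used brightness of the same kind. On day 1, 71 of 84, 31 of 37 and 29 of 51 members lay above the level expected. The other transcripts included those without a symbol, which lay -0.21 to -0.11 from named ones at matched brightness. An excess of that size, as for the initiation factors, may reflect this. A comparison with named genes alone was not run. Keratins and potassium channels had no direction that held over the scalings.

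The mean of 20 fatty acid oxidation genes was -1, -0.96 and -1.21 on the arrays of day 1 and -0.83, -0.98 and -1.31 on those of day 5, so that the arrays of day 5 that differed in macrophage genes lay together in these. On day 3 it was -1.54 on replicate 2, 0 on replicate 3 and 0.24 on replicate 4. The mean of proximal tubule markers varied too, between -0.83 and 0.1 on day 3. On day 5 it lay between -0.83, on replicate 5, and 0.32, on replicate 2. On day 1 it lay between -0.2 and 0.13. Whether the share of tubule RNA contributed to the fatty acid oxidation means was not tested.

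Transcripts of olfactory receptors, the odorant receptors of the nasal epithelium, were lower on every day than in the controls. Of 168 tested 85, 125, 109, 108 and 111 fell on days 1 to 5, with medians of -0.85, -1.33, -1.11, -1.2 and -1.14, or -0.56, -1.02, -0.86, -0.83 and -0.88 without control replicate 4, the array highest in them (0.64, against -0.33 and -0.34 on the other controls). Scaling between arrays is argued against with all controls kept, since the median nearest to 0 over 5 days and 5 scalings was -0.52. With these controls the median at matched brightness lay below that of other transcripts by 0.52 or more (-0.52 on the day nearest to 0). Neither comparison was repeated without control replicate 4. Probes well above background on the controls alone could also enter the tests, which favours a fall. Whether a difference that depends on brightness accounts for the falls therefore stays open. Genomic DNA or unprocessed RNA in the control arrays is a candidate explanation: at matched brightness transcripts without a symbol lay below named ones by -0.19, -0.11, -0.17, -0.19 and -0.21 on days 1 to 5, where at least 0.1 had been asked for, so that day 2 passed narrowly. No biological explanation was tested.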
